A study of Caenorhabditis elegans with 14 samples.

How the data were processed

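Total RNA of 14 synchronized populations of mid-L3 larvae, 7 wild type (N2) and 7 nhr-8(hd117), was labelled with Cy3 and hybridised to one-colour Agilent C. elegans arrays of 44381 features, per the labels' protocols and the file headers. The genotype and replicate number come from the labels. The populations are stated to be independent, so the spread between arrays includes that between cultures.

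The deposited scanner files hold spot intensity values on a linear scale. Per the file headers, the processed intensity was made by Agilent Feature Extraction with background subtraction and spatial and multiplicative detrending within the array, and was not normalized between arrays. Mean signal and local background intensity were taken from the same deposited files. Per the file headers, other columns hold flags (0 or 1) for signal well above background, saturation and outlier spots. The headers divide the arrays into 2 sets. Replicates 1 to 3 were extracted with version 9.5.3.1 from 1 scan pass, and replicates 4 to 7 with version 9.5.1.1 from 2 passes under an earlier protocol. The headers mark replicates 1 to 3 as an extended dynamic range extraction and replicates 4 to 7 as not. The arrays lie on 4 slides: one with 3 wild-type arrays and 1 mutant array, one with 2 mutant arrays, and a pair with 2 arrays of each genotype. The deposited value table holds log2 values of 30051 features, keyed by feature number. Its columns have nearly equal quartiles and medians near 10.7 (10.657 to 10.699), and correlated with the logarithm of the mean signal of the same array. The labels list limma among the submitters' processing notes. Which background correction and filter made the table stays unknown, as does whether further centring was applied. The table was used as an alternative. There were 0 columns of other series.

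For the main analysis, the log2 processed signal was scaled by subtracting each array's 75th percentile over the 42964 non-control features. Outlier spots were left out, saturated spots were kept (per the file headers the saturation value was 65227 to 65228 in the second set and 604664 to 606530 in the first), and the spots of a probe were averaged. Probes well above background on at least 7 of 14 arrays were kept (16251 of 20401). Gene names came from the sequence names in the files, matched to locus tags, or else synonyms, of the WBcel235 gene table: 19057 probes matched, 1344 did not and keep the file's name, and 565 of the latter have no sequence name. For genes with several probes, the probe with the highest mean signal was used. Of 744 such genes, 5 had probes called in opposite directions. This left 15399 genes, of which 347 are features without a gene name.

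Genotypes were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with array set as a covariate, chosen before the data were examined, and Benjamini-Hochberg adjustment at 0.05. P-values are two-sided unless said otherwise. The interaction of genotype and array set was fitted with the same tools, and each set and slide was also fitted alone. A log2 fold change is mutant minus wild type. The shift of a gene list is the median log2 fold change of its genes minus that of all genes, a reference adopted after seeing the data. Where a gene was not well above background on any array of a group, a bound is given. It sets the brighter group's mean against, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The 34 gene lists, among them 7 of tissue, germline and sperm markers, were written before the data were examined. They were tested with camera in limma at a preset correlation of 0.01, and again with the correlation estimated per list, with adjustment over the 34 lists. In places the adjusted p of the latter is given as that with an estimated correlation. The named genes follow a rule set at the same time. It takes nhr-8, the 12 largest increases and 12 largest decreases among called genes with one sign in both array sets, up to 4 members of each list with the lowest adjusted p, and all members of the sterol hormone list.

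The model was tested on simulated data: 200 of 15399 genes were changed, with the means of the real arrays, the spread within each genotype and array set, and no interaction. Genes were drawn independently, so correlated lists were not tested. Of 50 genes each changed by 0.25, 0.5, 1 and 2 on the log2 scale, 48%, 62%, 88% and 98% were called in the right direction, and 0.0395% of unchanged genes were called. These rates hold for genes with an equal change in both sets. In the real data the change differed between sets at 7293 genes, which adds to the spread. The rates therefore cannot be carried over to the real fit. A simulated list shifted by 0.5 was called and 0 other lists were.

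Alternatives were quantile normalization, normexp (offset 50) on the mean and background signals, both together, the deposited table, no filter or a filter on all 14 arrays, the mean of probes, no array set, slide as a fixed or random block, replicate number as a block, each array set alone, array weights, a trended robust prior, an adjusted p of 0.01, an estimated correlation, the fry test, and leaving out each array. The sperm level as a covariate, leaving out genes saturated on any array, the genes called in both sets, and the alternatives of the count of genes that differ between sets were added after seeing the data, as were the fits within slides. The spread between replicate arrays (median absolute difference 0.0948 to 0.321) exceeded that between spots of one array (0.081). Repeat hybridisations of one RNA would do so too, so the independence of the populations rests on the labels alone.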

Results

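RNA from whole Caenorhabditis elegans larvae was measured on 14 one-colour microarrays, 7 of the wild-type strain N2 and 7 of the mutant nhr-8(hd117). nhr-8 encodes a nuclear hormone receptor of the family that includes the sterol hormone receptor daf-12 and the vertebrate sterol and xenobiotic sensors. Worms cannot make sterols and take them from the diet. According to the labels, each array holds an independent synchronized population, grown at 25 °C without added cholesterol and collected in the middle of the L3 larval stage. The comparison asks which transcripts differ between the genotypes when dietary sterol is low. The arrays fall into 2 sets, each with both genotypes: replicates 1 to 3 (the first array set, 3 against 3) and replicates 4 to 7 (the second array set, 4 against 4). Between 75.5% and 86.7% of probes were well above background on an array. Saturated spots were found only in the second set (667 to 801 per array, none in the first), whose signals end near 15.99 on the log2 scale, against 19.2 in the first set. They touch 500 of 15399 genes, 267 of them on all arrays of the second set. The change of such a gene in that set is held back or fixed by the ceiling, so its size and its difference between sets are not read as expression. The counts of called genes below include such genes unless said otherwise. The number of arrays limits the precision, so values are given for all 14 arrays and within each set.

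nhr-8 itself was lower in every mutant population than in every wild-type population of its set. The log2 fold change was -2.53 ± 0.08 (SE, 7 against 7 arrays, limma adjusted p = 5.65e-10), so the mutant signal was 17.3% of the wild-type signal. In the first array set the change was -2.67 (adjusted p = 9.43e-06) and in the second it was -2.44 (adjusted p = 3.88e-06). Within the 3 slides that held both genotypes it was -2.58, -2.41 and -2.46. A further probe of the gene gave -2.50 ± 0.08 (SE). Both probes lie on chromosome IV (7712593 to 7712698 and 7712594 to 7712702, as the array files give them; the genome build is not given in the sources used here). They overlap almost fully, so they are not independent checks. Whether they lie inside the part deleted in hd117 was not determined here, and the signal stayed well above background on all 14 arrays. The size of the change was smaller after normexp background correction with quantile scaling (-1.62) and in the deposited value table (-1.35).

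**Figure D1:**
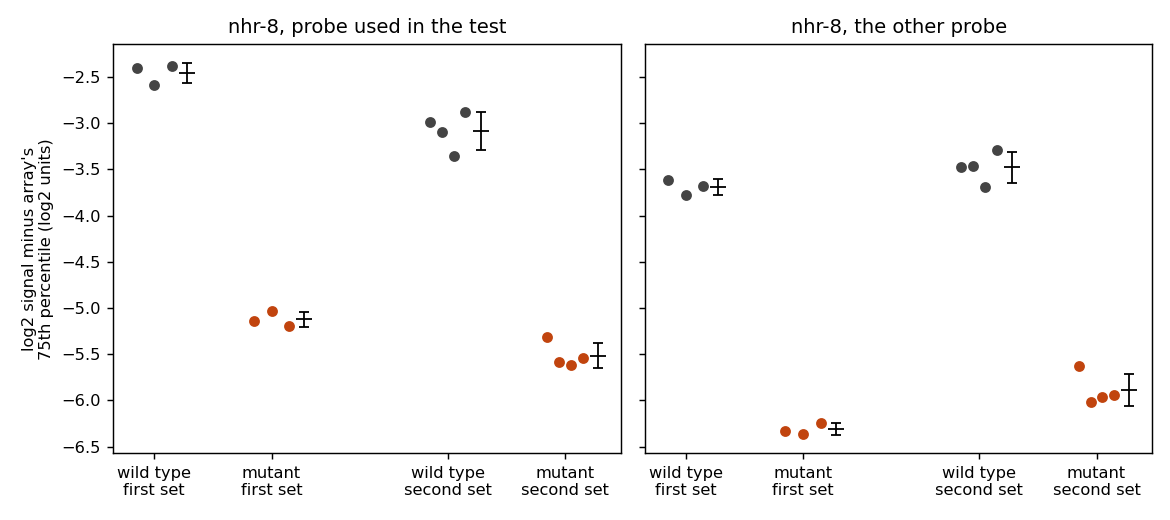
Signal of the 2 nhr-8 probes on each array, as log2 signal minus the array's 75th percentile. Points are arrays and bars are the mean ± SD of each genotype and array set. On the probe used in the test, the mutant arrays of the first set average -5.12 and the wild-type arrays -2.46.

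The genotypes differed at a large share of genes. Of 15399 genes tested, 6301 passed an adjusted p of 0.05 (limma, array set as covariate), 2954 higher and 3347 lower in the mutant, and 1548 of them changed at least 2-fold (1287 higher and 261 lower). Of the 6301, 1116 had opposite signs in the 2 array sets, so their direction over all arrays is only an average. The number of genes past the threshold and at least 2-fold was 618 with normexp, and it ranged from 941 to 1801 when each array was left out in turn. The split between genes higher in the mutant and genes lower in the mutant depends on scaling: it was 2418 and 4491 after quantile normalization, 806 and 1844 with normexp, 2562 and 4470 with both, and 2292 and 4000 in the deposited table. Fitted alone, the first array set gave 7620 genes (3432 higher, 4188 lower) and the second 8645 (3971 higher, 4674 lower). A total of 2759 genes passed in both sets with one direction, 1173 higher (885 expected from independent lists) and 1586 lower (1271 expected). Another 2211 genes passed in both sets with opposite directions, 1389 lower in the first set and higher in the second (1080 expected) and 822 the other way (1042 expected). Of the genes of one direction, 378 changed at least 2-fold in each set, 261 higher and 117 lower.

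The 12 largest increases of one sign in both array sets included 4 C-type lectin genes and 3 claudin-like genes. The C-type lectin genes clec-46 (log2 fold change 7.32 ± 0.18, SE, adjusted p = 5.18e-11), clec-45 (6.60 ± 0.29), clec-240 (4.99 ± 0.58) and clec-70 (4.98 ± 0.28) rose, as did the claudin-like genes clc-11 (6.97 ± 0.20) and clc-12 (5.47 ± 0.62). clec-240 was above background on 6 of 7 wild-type arrays, and spots of clec-45 were saturated on 3 mutant arrays and of clc-11 on 4, so the sizes measured for these 3 genes are limited. clc-13 was not well above background on any wild-type array and was at least 81.7-fold higher in the mutant (adjusted p = 5.21e-08). ugt-15, of the UDP-glucuronosyltransferases that conjugate small molecules, rose by 6.20 ± 0.20 and was above background on 4 of 7 wild-type arrays, so background limits the size measured. The chemoreceptor-family gene sri-36 rose (adjusted p = 1.88e-06) and was above background on 1 of 7 wild-type arrays, so no exact size is given. The tetraspanin gene tsp-1 (5.10 ± 0.39) and the genes ZK1290.10 (5.36 ± 0.44) and ZK896.1 (5.25 ± 0.21) complete the 12 largest increases. The calls of clc-13 and sri-36 were lost with normexp background correction. Several of these genes have close relatives in the genome (clec-45 and clec-46, the clc genes), and their probes could share signal.

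The 12 largest decreases of one sign in both sets included lipl-5, lips-14 and fat-5. The lysosomal lipase-like gene lipl-5 fell by 3.69 on the log2 scale (SE 0.08, adjusted p = 1.94e-11), and lips-14, a lipase-related gene, fell by 2.98 (SE 0.19). fat-5, which encodes a palmitoyl-CoA desaturase, fell by 2.81 (SE 0.39, adjusted p = 0.000129). The cytochrome P450 gene cyp-14A2 fell by 2.77 and ugt-33 fell by 2.96. The lectin gene clec-206 fell by 4.24, and the saposin-like gene spp-17 fell (adjusted p = 4.54e-07). scl-11 was not well above background on any mutant array and was at least 26.7-fold lower there (adjusted p = 4.41e-07). C17F4.7 fell (adjusted p = 1.44e-06), C31B8.12 fell by 3.51 and F45D11.2 fell by 3.40, and H25K10.1 fell (adjusted p = 6.92e-06). Of the mutant arrays, 4 of 7 measured clec-206 above background, 2 of 7 measured H25K10.1, 5 of 7 measured C31B8.12 and 6 of 7 measured lips-14, so background limits the sizes measured for these genes. spp-17 and C17F4.7 were saturated on all 4 wild-type arrays of the second set, so no exact size is given, and lipl-5 was saturated on 1 wild-type array.

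**Figure D2:**
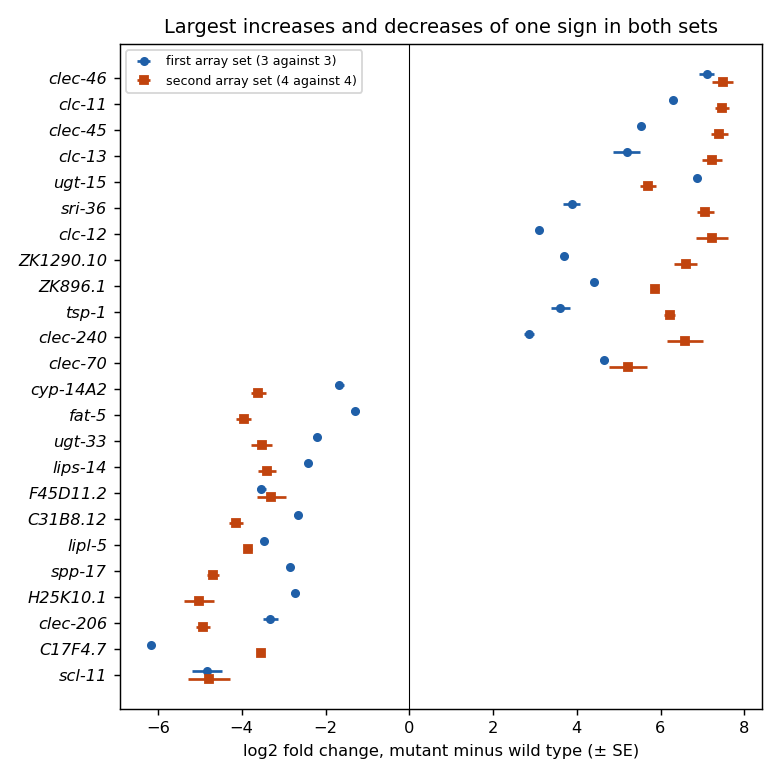
Log2 fold change (mutant minus wild type, ± SE) of the 12 largest increases and 12 largest decreases among genes of one sign in both array sets. Circles are the first set and squares the second. Sizes are limited by background for genes not above it on every array, and by saturation for clec-45, clc-11, spp-17, C17F4.7 and lipl-5. For clec-46 the change was 7.10 in the first set and 7.48 in the second.

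Genes of sterol hormone synthesis and sensing moved in both directions. Of the 10 measured, 5 were higher, 3 were lower, nhr-8 itself among them, and 2 did not pass (5 and 3 when adjusted over the list alone). daf-9, the cytochrome P450 of the last step of dafachronic acid synthesis, rose by 0.41 ± 0.05 (SE, adjusted p = 2.33e-05), and dhs-16, a dehydrogenase of that pathway, rose by 0.56 ± 0.11. daf-36, which encodes the oxygenase that acts on cholesterol early in the pathway, fell by 0.51 (SE 0.10, adjusted p = 0.00207). ncr-1, a Niemann-Pick C1 homologue that handles sterols, rose by 0.51 ± 0.11. daf-12 rose by 0.31 ± 0.11 over all arrays, with 0.69 in the first array set and 0.02 in the second (adjusted p = 0.810), and its call was lost under 4 other ways of scaling or background correction and in 8 of the 14 fits that left out an array. emb-8 fell by 0.31, with -0.03 in the first set (adjusted p = 0.512) and -0.52 in the second. ncr-2 went opposite ways, -0.45 in the first set (adjusted p = 0.00186) and 3.15 in the second (adjusted p = 0.000151). din-1 (-0.10, adjusted p = 0.443) and strm-1 (-0.07, adjusted p = 0.817) did not pass. With normexp the calls of dhs-16, ncr-1, emb-8 and ncr-2 were lost. The list as a whole did not pass (shift 0.15, camera adjusted p = 0.841, estimated correlation 0.863).

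The mevalonate pathway, which in worms serves isoprenoids and not sterols, had 5 of 10 genes lower, none higher and 5 not passing (6 lower when adjusted over the list alone). coq-1 (-0.46 ± 0.05), hmgs-1 (-0.34 ± 0.05) and Y48B6A.13 (-0.48 ± 0.07) fell in both array sets. A list's shift is the median log2 fold change of its genes minus that of all genes. It was -0.15 here (camera adjusted p = 0.0251; adjusted p = 0.666 with an estimated correlation), and with normexp it turned to 0.10. The shift of the mevalonate pathway also lost its call under quantile scaling (-0.0027), with normexp and quantile together (-0.031) and in the deposited table (-0.024).

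Genes of fat breakdown were mostly lower. Of 15 peroxisomal beta-oxidation genes, 12 fell, 2 rose and 1 did not pass, with the same counts when adjusted over the list alone, and 10 fell in both array sets. daf-22, the thiolase of ascaroside side-chain shortening, fell by 0.73 (SE 0.08, adjusted p = 1.29e-05), and the peroxisomal catalase gene ctl-2 fell by 0.57 (SE 0.05). The members that rose were ech-9 (3.45 ± 0.35) and acox-1.5 (0.88 ± 0.09). The list's shift was -0.50 (camera adjusted p = 0.00301; adjusted p = 0.559 with an estimated correlation), with -0.40 in the first set and -0.37 in the second. On single slides it was -0.37, -0.40 and -0.43, and with slide as a block -0.44. Its call was lost under quantile scaling (adjusted p = 0.0861), normexp (0.139), both (0.0551) and in the deposited table (0.0592), with the same sign in each. Of 18 mitochondrial fatty acid oxidation genes, 12 fell, 1 rose and 5 did not pass, unchanged when adjusted over the list alone. Of the 15 never saturated, 9 fell and 1 rose. cpt-3, a carnitine palmitoyltransferase gene, fell (adjusted p = 0.000477, above background on 3 of 7 mutant arrays) and acdh-13 fell by 0.44 (SE 0.07). For this list the shift was -0.26 (camera adjusted p = 0.0157; adjusted p = 0.559 with an estimated correlation) and turned to 0.03 with normexp, where the call of cpt-3 was lost. The list's call was also lost under quantile scaling, with normexp and quantile together and in the deposited table.

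Among other lipid genes, 9 of 21 fatty acid synthesis and desaturation genes were lower, 2 were higher and 10 did not pass (9 and 2 when adjusted over the list alone). Of the 17 never saturated, 6 were lower and 2 higher, and without saturated genes the list's camera adjusted p was 0.227. Besides fat-5, the elongase gene elo-1 (-0.53 ± 0.09) and the receptor gene nhr-80 (-0.47 ± 0.08) fell, and sbp-1, the worm SREBP homologue, rose by 0.30 ± 0.06. The list's shift (-0.35, camera adjusted p = 0.0702, estimated correlation 0.859) lay in the second set (-0.56) and not in the first (0.03). That difference between sets passed (interaction adjusted p = 0.00079; adjusted p = 0.414 with an estimated correlation), and the second set is the one in which sperm genes were raised. Of 13 lipases and lipid storage genes, 3 rose, 4 fell and 6 did not pass (4 and 4 when adjusted over the list alone). lipl-3 (-1.86 ± 0.18) and lipl-4 (-1.36 ± 0.16) fell with lipl-5, and the fasting-induced lipase gene fil-1 rose by 1.51 ± 0.09. The list's shift was 0.00 (adjusted p = 0.673) while its mean shift was -0.43. Of 16 lipid-binding protein genes, 4 rose, 3 fell and 9 did not pass (4 and 3 when adjusted over the list alone). Saturated spots touched 4 of the 16, on all arrays of the second set. Of the 12 others, 4 rose and 1 fell. lbp-7 rose by 0.38 ± 0.06, and the list's shift was -0.07 (adjusted p = 0.904; mean shift 0.03).

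Of 15 phosphatidylcholine and one-carbon genes, 1 rose, 3 fell and 11 did not pass (1 and 3 when adjusted over the list alone). The choline kinase gene ckb-2 rose by 0.59 ± 0.13. sams-1, which encodes S-adenosylmethionine synthetase, was 0.15 in the first set (adjusted p = 0.0974) and -1.77 in the second (adjusted p = 6.05e-06). The list did not pass (shift -0.05, adjusted p = 0.621), but its difference between sets did (interaction adjusted p = 0.0099; adjusted p = 0.414 with an estimated correlation). Of 7 vitellogenin and yolk uptake genes, 1 rose, 2 fell and 4 did not pass, the same when adjusted over the list alone. The yolk protein genes vit-2 (-1.42 ± 0.16) and vit-1 (-1.09 ± 0.15) fell, and the yolk receptor gene rme-2 rose by 0.64 ± 0.10. vit-5 was -0.30 in the first set (adjusted p = 0.0297) and 1.02 in the second (adjusted p = 0.00793). The shift of the list was 0.07 (adjusted p = 0.888; mean shift -0.32), and its sign depended on single arrays (-0.043 to 0.28 when each was left out).

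Detoxification families held large changes in both directions. Of 66 cytochrome P450 genes, 23 rose, 17 fell and 26 did not pass (25 and 21 when adjusted over the list alone). cyp-35A5 (-2.58 ± 0.18) and cyp-35A2 (-1.43 ± 0.12), of a subfamily induced by xenobiotics, fell. cyp-33C9 rose by 0.92 ± 0.09, and cyp-36A1 rose by 2.07 ± 0.15, a call lost with normexp. Of 62 UDP-glucuronosyltransferase genes, 13 rose, 24 fell and 25 did not pass (13 and 25 when adjusted over the list alone). ugt-44 rose by 2.73 ± 0.14, with 2 mutant arrays saturated, and ugt-53 fell by 1.77 (SE 0.07, adjusted p = 1.85e-09). Of 46 glutathione S-transferase genes, 12 rose, 15 fell and 19 did not pass (12 and 16 when adjusted over the list alone). gst-4, a target of the oxidative stress factor SKN-1, fell by 1.79 (SE 0.14), and gst-22 rose by 2.18 ± 0.19. Of 38 P-glycoprotein and ABC transporter genes, 10 rose, 16 fell and 12 did not pass, unchanged when adjusted over the list alone. pgp-13 fell by 1.95 (SE 0.11), pgp-9 fell by 0.87 (SE 0.09) and abt-4 rose by 2.02 ± 0.15. Of 30 short-chain dehydrogenase genes, 6 rose, 13 fell and 11 did not pass (7 and 14 when adjusted over the list alone). dhs-30 rose by 2.09 ± 0.15 and dhs-2 fell by 1.36 (SE 0.12). The shifts of these 5 lists were 0.02, -0.15, 0.03, -0.06 and -0.14, with camera adjusted p of 0.591, 0.196, 0.904, 0.621 and 0.264. The fry test, which does not set a list against other genes, called the UDP-glucuronosyltransferases (adjusted p = 2.82e-05), ABC transporters (0.000147) and short-chain dehydrogenases (0.00278).

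Among 206 nuclear hormone receptor genes, 57 rose, 33 fell and 116 did not pass, the same when adjusted over the list alone. nhr-50 rose by 1.16 ± 0.09 over all arrays (0.87 in the first set and 1.38 in the second), and nhr-98 (1.37 ± 0.09) and nhr-203 (0.56 ± 0.04) rose with calls that were lost with normexp. The receptor shift was 0.11 (camera adjusted p = 0.0251; adjusted p = 0.815 with an estimated correlation), 0.13 in the first set and 0.14 in the second. It kept its sign and lost its call under quantile scaling (adjusted p = 0.485), normexp (0.692), both (0.532), in the deposited table (0.291) and with slide as a block (0.0686). Its mean shift was -0.02, and the direction depends on the reference: without subtracting the median of all genes, the list median of 0.08 turned to -0.06 under quantile normalization, -0.21 with normexp, -0.03 with both and -0.02 in the deposited table.

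Stress genes changed in small numbers. Of 13 heat shock genes, 1 rose, 3 fell and 9 did not pass, and of 16 unfolded protein response genes, 1 rose, 2 fell and 13 did not pass. Adjusted over the list alone, the counts were 1 and 3, and 1 and 1. The small heat shock genes hsp-12.3 (-1.42 ± 0.15) and hsp-16.2 (-0.99 ± 0.20) fell. hsp-4, the endoplasmic reticulum BiP gene, rose by 0.61 ± 0.07, and the mitochondrial chaperone gene hsp-6 fell by 0.60 (SE 0.05). Neither list passed (shifts -0.12 and -0.05, adjusted p = 0.546 and 0.621). Of 26 insulin pathway genes and targets, 5 rose, 10 fell and 11 did not pass, unchanged when adjusted over the list alone. dod-24 (2.04 ± 0.11, 1 mutant array saturated) and dod-22 (2.83 ± 0.28), named for their response to daf-16, rose, and the catalase gene ctl-1 fell by 0.57 (SE 0.06). The insulin shift was -0.13 (adjusted p = 0.621).

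C-type lectin genes and antimicrobial genes changed in both directions. Of 136 C-type lectin genes, 49 rose, 32 fell and 55 did not pass (54 and 32 when adjusted over the list alone), 39 and 27 of them in both array sets. clec-71 rose by 2.37 ± 0.07 (adjusted p = 4.06e-10), and clec-169 fell by 2.28 (SE 0.09). Of 91 antimicrobial peptide and lysozyme genes, 20 rose, 24 fell and 47 did not pass (21 and 26 when adjusted over the list alone). The thaumatin-family genes thn-1 (-2.07 ± 0.08) and thn-2 (-2.10 ± 0.09), the invertebrate lysozyme gene ilys-2 (-1.97 ± 0.07) and the saposin-like gene spp-4 (-1.63 ± 0.07) fell. Neither list passed (shifts 0.05 and 0.16, adjusted p = 0.141 and 0.903; mean shift of the latter -0.12). Of 186 F-box genes, which encode substrate adaptors of ubiquitin ligases, 74 rose, 18 fell and 94 did not pass (79 and 18 when adjusted over the list alone). fbxa-88 rose by 3.60 ± 0.12 and fbxa-59 by 0.97 ± 0.07. The F-box shift was 0.24 (camera adjusted p = 1.59e-05; adjusted p = 0.815 with an estimated correlation) and turned to -0.21 with normexp. Without subtracting the median of all genes, the list median of 0.22 also turned under quantile normalization (-0.04). The shift was 0.08 in the first set and 0.46 in the second (interaction adjusted p = 2.91e-05; adjusted p = 0.496 with an estimated correlation), the set with raised sperm genes. F-box genes are dim: in the second set the unscaled median log2 signal of the list was 7.49 in wild type and 8.64 in the mutant. Whether signal near background makes part of this difference was not tested.

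Genes of the moulting cycle differed between the sets, and collagen and dauer-linked genes did not pass that test (interaction adjusted p = 0.836 and 0.355). Of 157 collagen genes, 13 rose, 15 fell and 129 did not pass (7 and 9 when adjusted over the list alone). col-158 rose by 1.68 ± 0.30, and the list's shift was -0.07 (adjusted p = 0.888). The sign of that shift depended on single arrays (-0.089 to 0.018 when each was left out). Saturated spots touch 55 of the collagen genes, 22 of them on all arrays of the second set. Of the 102 others, 7 rose and 5 fell, and without the 55 the shift was -0.015. Of 27 genes of the moulting cycle, 1 rose, 1 fell and 25 did not pass over all arrays (0 and 0 when adjusted over the list alone), and the list did not pass (shift -0.45, adjusted p = 0.202). Within the sets, however, 14 of the 27 passed in both with opposite directions. The moulting list was shifted by 0.28 in the first set (camera adjusted p = 5.07e-05; adjusted p = 0.740 with an estimated correlation) and by -0.86 in the second (adjusted p = 0.0125; adjusted p = 0.791 with an estimated correlation). noah-1, an apical matrix gene, was 0.20 in the first set (adjusted p = 0.0336) and -1.85 in the second (adjusted p = 0.00511). The difference between sets passed (interaction adjusted p = 0.000674; adjusted p = 0.650 with an estimated correlation). Of 21 dauer-linked genes, 6 rose, 5 fell and 10 did not pass, the same when adjusted over the list alone. The insulin-like gene ins-4 rose by 0.99 ± 0.14 and daf-5 rose by 0.58 ± 0.12, both calls lost with normexp. The dauer list did not pass (shift 0.08, adjusted p = 0.621).

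Most ribosomal protein genes could not be measured in the second array set. Of the 74, 67 had saturated spots there, 66 on all 8 arrays, and the unscaled median log2 signal of the list was 15.97 in both genotypes. Scaling then sets their difference in that set, because the 75th percentile subtracted was 0.25 higher in the mutant arrays. The count (23 lower, none higher and 51 not passing; 18 lower when adjusted over the list alone), the shift of -0.12 (camera adjusted p = 4.75e-06; adjusted p = 0.859 with an estimated correlation) and the values of 0.02 in the first set and -0.19 in the second (interaction adjusted p = 0.000102; adjusted p = 0.772 with an estimated correlation) therefore say little about expression. The shift was 0.10 under quantile scaling, 0.20 with normexp and 0.05 with both. Of the 7 genes never saturated, 6 were lower, among them rpl-18A, which fell by 0.67 (SE 0.07), and rpl-29, which fell by 0.44 (SE 0.06). The 7 ribosomal genes did not pass the test of the difference between sets (adjusted p = 0.286). Of 36 histone genes, 1 rose, 5 fell and 30 did not pass (0 and 2 when adjusted over the list alone). The linker histone gene his-24 fell by 0.75 (SE 0.13). his-70 was -0.98 in the first set (adjusted p = 4.03e-05) and 6.45 in the second (adjusted p = 8.53e-06). The histone shift was -0.18 (camera adjusted p = 0.029; adjusted p = 0.863 with an estimated correlation) and turned to 0.08 with normexp. Its call was also lost under quantile scaling, with normexp and quantile together, in the deposited table and with slide as a block (camera adjusted p = 0.0926). It was lost too in 5 of the 14 fits that left out an array. Of 11 housekeeping reference genes, 1 rose, 4 fell and 6 did not pass, unchanged when adjusted over the list alone (shift -0.10, adjusted p = 0.303).

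Markers of the main tissues showed small shifts. Of 19 intestine markers, 2 rose, 9 fell and 8 did not pass (2 and 10 when adjusted over the list alone). The gut esterase gene ges-1 fell by 0.88 (SE 0.08), and the intestinal transcription factor gene elt-7 fell by 0.47 (SE 0.09). The intestine shift was -0.13 (camera adjusted p = 0.107), -0.01 in the first set and -0.18 in the second. Of 16 epidermis markers, 2 rose, 1 fell and 13 did not pass. Of 15 body wall muscle markers, 5 fell and 10 did not pass. Of 15 pharynx markers, 4 rose, 2 fell and 9 did not pass. These 3 counts were unchanged when adjusted over the list alone. Of 24 neuron markers, 2 rose, 3 fell and 19 did not pass (1 and 1 when adjusted over the list alone). The shifts of these 4 lists were -0.01, -0.08, -0.10 and -0.04 (camera adjusted p = 0.980, 0.141, 0.871 and 0.904). The muscle and neuron lists differed between sets (interaction adjusted p = 0.0324 and 0.0369; adjusted p = 0.507 and 0.496 with an estimated correlation). Of the muscle markers 7 were saturated on all arrays of the second set, and without them the muscle difference did not pass (adjusted p = 0.205). Of the 8 others, 3 fell. Their shift was 0.01 in the first set and -0.19 in the second, against 0.05 and -0.19 with all markers. The lost call thus does not show that saturation made the difference. Of the intestine markers 6 were saturated on some array. Of the 13 others, 6 fell and 2 rose, and without the saturated markers the shift was -0.078. pha-4, the pharynx organ identity gene, rose by 0.66 in the first set (adjusted p = 0.000261) and was 0.17 in the second (adjusted p = 0.0512).

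Germline and above all sperm genes separated the array sets. Of 41 sperm markers, including the major sperm protein genes, 34 were higher over all arrays, none was lower and 7 did not pass (39 higher when adjusted over the list alone). The change ran opposite ways: 38 of the 41 passed in both sets with opposite directions. Saturated spots touched 11 of the 41. Of the 30 others, 23 were higher and none was lower, with shifts of -1.13 in the first set and 6.14 in the second. The sperm shift was -1.23 in the first set (camera adjusted p = 1.24e-10; adjusted p = 0.815 with an estimated correlation) and 6.25 in the second (adjusted p = 8.68e-22; adjusted p = 0.490 with an estimated correlation). The interaction adjusted p was 1.14e-28 (adjusted p = 0.414 with an estimated correlation). Over all arrays the shift was 3.00 (camera adjusted p = 8.07e-07; adjusted p = 0.859 with an estimated correlation). On single slides it was -1.39 on that of the first set and 5.93 and 6.54 on those of the second. The list's median log2 level was -2.44 ± 0.13 (SD, n = 3) in wild type and -3.65 ± 0.25 (n = 3) in the mutant of the first set. In the second set it was -4.20 ± 0.12 (SD, n = 4) in wild type and 0.78 ± 0.70 (n = 4) in the mutant. nspd-1, a sperm-enriched gene above background on 4 of 7 wild-type arrays, which limits the sizes measured, was -1.27 in the first set (adjusted p = 0.00135) and 9.28 in the second (adjusted p = 1.54e-05). Of 31 germline markers, 11 rose, 3 fell and 17 did not pass, the same when adjusted over the list alone. The RNA-binding protein genes puf-3 (0.28 ± 0.06) and puf-5 (0.67 ± 0.15) rose, the latter call lost with normexp. The germline shift was 0.25 (camera adjusted p = 0.0251; adjusted p = 0.859 with an estimated correlation), -0.05 in the first set and 0.46 in the second (interaction adjusted p = 2.91e-05; adjusted p = 0.496 with an estimated correlation). The list of germline markers lost its call with array weights (0.10) and with the sperm level as a covariate (0.021).

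**Figure D3:**
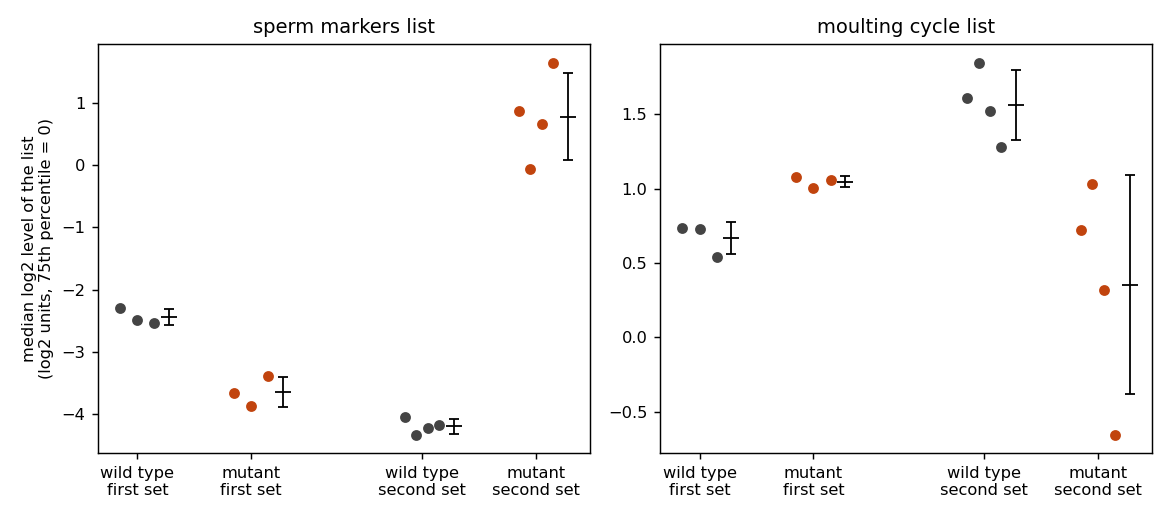
Median log2 level of the sperm marker list and of the moulting cycle list on each array, where 0 is the array's 75th percentile. Points are arrays and bars are the mean ± SD. The 4 mutant arrays of the second set lie between -0.06 and 1.65 for sperm markers, and all other arrays lie at -2.30 or below.

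The genotype difference itself differed between the array sets at 7293 genes (limma interaction, adjusted p under 0.05), by at least 2-fold at 2569 of them. Across genes, which are not independent replicates, the log2 fold changes of the sets correlated with Pearson r = -0.14 and Spearman rho = 0.00. Their SD was 0.52 in the first set and 1.46 in the second. The mutant arrays of the second set stood apart from the rest on the first principal component (82.8 to 138, 49.5% of the variance), where the remaining arrays lay between -76.6 and -17.9. In all, 9 of the 34 lists passed over all arrays, 4 in the first set alone, 10 in the second alone, and 9 in the test of the difference between sets. Without the genes saturated on any array, 7 passed that last test. None of the list calls over all arrays or between sets held with an estimated correlation.

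**Figure D4:**
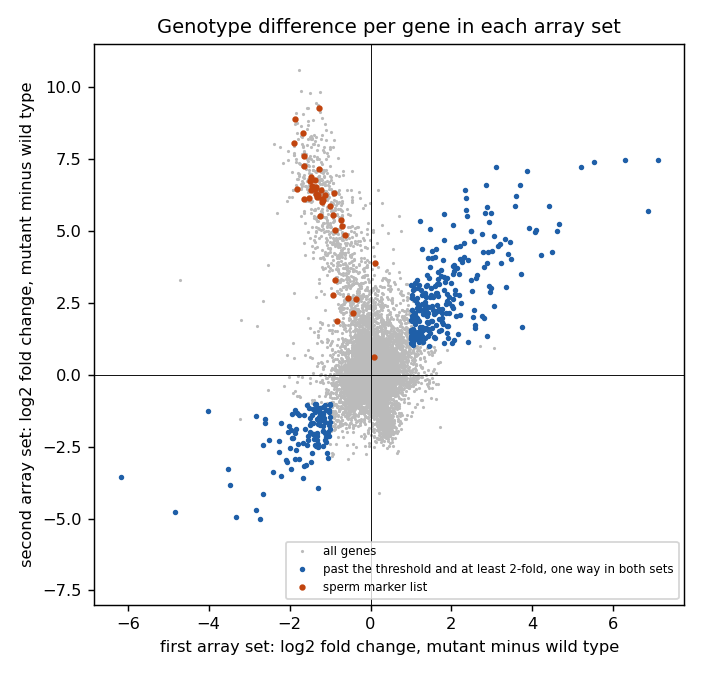
Log2 fold change (mutant minus wild type) of each gene in the first array set (horizontal) and in the second (vertical). Grey points are all genes, blue points the 378 genes at least 2-fold changed one way in both sets, and orange-red points the 41 sperm markers.

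**Figure D5:**
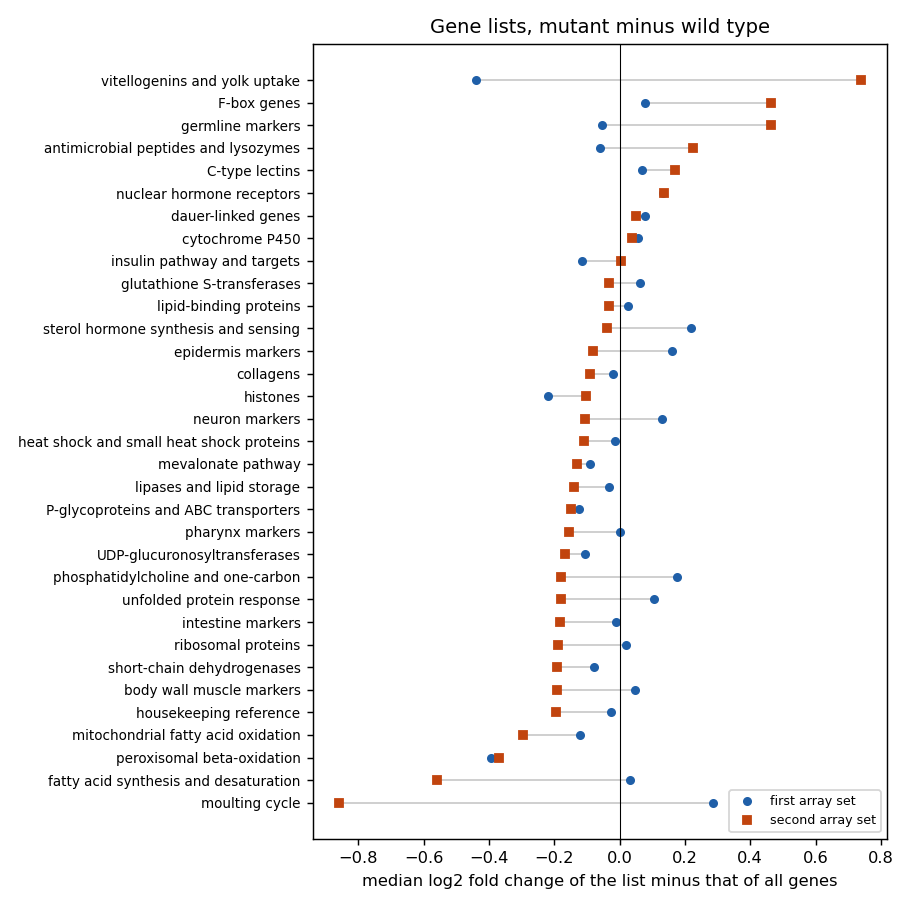
Shift of each gene list, as the median log2 fold change of its genes minus that of all genes, in the first array set (circles) and the second (squares). The sperm list (-1.23 and 6.25) is left out for scale. The peroxisomal list lies at -0.40 and -0.37. Most ribosomal genes are saturated in the second set.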

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

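The patterns below came from the data. The tests of the scanner, of scaling on the sperm list, of the intestinal share and of the sperm level as a covariate were chosen after the result was seen. The splits of arrays and the bounds of the age test were set before their results, but the arrays of the age test were picked once their sperm levels were known. The comparisons of array sets were planned.

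The genotype difference differed between the array sets at 7293 genes. Among the lists, the median over genes of the difference between the effects (second set minus first) was 7.52 for sperm markers, -1.34 for the moulting cycle, 0.51 for germline markers and 0.41 for F-box genes. It was -0.40 for fatty acid synthesis and desaturation, -0.30 for phosphatidylcholine and one-carbon genes and -0.21 for neuron markers. It was -0.26 for ribosomal proteins and -0.29 for body wall muscle markers, but 67 of 74 and 7 of 15 of these genes were saturated in the second set, where scaling sets their difference. Without saturated genes neither list passed (adjusted p = 0.286 and 0.205), while the other 7 did. The 8 muscle markers left were still shifted by -0.19 in the second set and by 0.01 in the first. For muscle the lost call thus does not show that saturation made the difference. With all genes, each of the 9 lists passed the test of the difference with the preset correlation and none did with an estimated one. In 100 splits of the 14 arrays, 1 (the real one) gave as many genes that differ between sets, and the highest of the others gave 5112. An arbitrary grouping of the arrays thus does not account for this count. A split that mixes the genotypes also moves the difference shared by both sets into the spread. The splits therefore cannot tell whether an equal genotype difference in both sets, with variation between batches of cultures, would give such a count. For the 6301 genes called over all arrays, 1 of 100 splits (the real one) gave as many, and the highest other gave 5018. The same split gave both of these highest counts, and it exchanged a single pair of arrays between the genotypes. Within the second set, 1 of 35 splits (the real one) gave 8645 genes and the others gave 0 at most. The first set has only 10 splits, too few for a share under 0.05. Its real split gave 7620 genes, and the highest other gave 0.

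The number of lists called is different: 20 of 100 splits gave at least the 9 lists of the real split, and the highest other gave 13. Chance cannot be excluded for that count, and single list calls with the preset correlation carry little weight on their own.

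Sperm genes were higher in the mutants of the second set and lower in those of the first. Scanner and processing differences between the sets would shift both genotypes of a set alike, but the list's median level differed between genotypes by 1.21 in the first set and 4.98 in the second without overlap of arrays, which argues against them as the whole cause. The choice of scaling and background correction is argued against too, since under the 4 other ways the shift of the list kept its sign in each set and stayed at 0.85 or more in size. A difference in developmental age at harvest, opposite in the 2 sets, is a candidate explanation, with mutants ahead of wild type in the second set. Across 15360 genes outside the list, the difference between mutant replicates 7 and 5 of the second set correlated with the genotype difference of that set's other mutants (r = 0.53) and inversely, weakly, with that of the first set (r = -0.22; Spearman rho -0.18; -0.13 without the dimmest genes), which meets the bounds of 0.2 and -0.2, the latter only narrowly and not by the other 2 measures. Without the dimmest genes the correlation in the second set was 0.43. Signal level runs the same way on these arrays. The median signal was 633 on mutant replicate 5 and 845 on replicate 7. It was 860 and 721 on mutant replicates 4 and 6, and 498 to 527 on the wild-type arrays of that set. The correlation in the second set therefore cannot tell age from signal level. Other sources of sperm RNA, such as males, and a genuine effect of the genotype on timing stay open, and stage was not measured apart from these arrays.

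Peroxisomal beta-oxidation genes were lower in the mutant. A difference in age stays open. With the sperm level as a covariate the list's shift was -0.49 (adjusted p = 0.00289), against -0.50 without it, but the list fell in both sets, where the sperm level runs opposite ways, so this could hardly come out otherwise. Both calls use the preset correlation, and without the covariate the adjusted p was 0.559 with an estimated one. A smaller share of intestinal RNA stays open. The list lay below the intestine markers by 0.39 in the first set (permutation p = 0.0215) and by 0.19 in the second (permutation p = 0.109), so the test did not decide in both sets. An effect of the genotype on these genes also stays open, as the call depends on scaling.

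A lone array stood apart in 3 of 68 combinations of genotype and named gene, by a gap to the nearest array that is large against the group's range. The combinations do not cover all 157 named genes. The rule picks out about 1 in 20 by chance when 7 values share a single normal spread. The 7 arrays of a genotype come from 2 array sets, so that rate may not hold here. The 3 arrays are therefore not read as a finding. clec-70 in wild-type replicate 7 was at -8.28 with the next array at -6.73 (log2 level), F45D11.2 in wild-type replicate 6 was at 0.62 with the next at -0.28, and ugt-33 in mutant replicate 7 was at -5.43 with the next at -4.60.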

How the results depend on the processing

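The alternatives were set before the data were examined, except the sperm level as a covariate, leaving out saturated genes, the count of genes called in both array sets and the alternatives of the count that differs between sets, which were added after the result was seen. One further choice was made late: list shifts are given relative to the median of all genes, and this was adopted after raw list medians under the alternatives had been seen. The choice changes the direction of 6 called lists under one alternative or another. As a raw median, nuclear hormone receptors (0.08) turned to -0.06 under quantile normalization, -0.21 with normexp, -0.03 with both and -0.02 in the deposited table. F-box genes (0.22) turned to -0.04, -0.44 and -0.02 under the first 3 and stayed at 0.01 in the table. The median of all genes itself moved from -0.03 to -0.11 under quantile normalization and -0.23 with normexp. Relative to it, receptors keep their sign and F-box genes turn only with normexp, while ribosomal, mevalonate, mitochondrial and histone lists turn in places where their raw medians do not. Raw medians of several lists that did not pass, C-type lectins and dauer-linked genes among them, also turned. Directions of small list shifts therefore depend on the reference chosen.

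Fewer genes passed with normexp, which also replaces the processed signal by the mean signal and adds an offset, but not with normexp and quantile together (7032 genes past the threshold). With normexp alone 2650 genes passed (806 genes higher in the mutant, 1844 genes lower in the mutant), and the number of genes past the threshold and at least 2-fold was 618. The number of genes past the threshold in both array sets, same direction, was 536, and 2389 genes had a difference between array sets. The genes lbp-8 (-0.65), fbxa-134 (-0.26), daf-28 (-0.074) and elt-1 (-0.14) reversed. The shifts of the mevalonate pathway (0.10), mitochondrial fatty acid oxidation (0.033), F-box genes (-0.21), ribosomal proteins (0.20) and histones (0.084) reversed, those of peroxisomal beta-oxidation (-0.23) and nuclear hormone receptors (0.022) lost their calls, and 2 lists passed. Of 157 named genes, 45 lost their call. The offset compresses changes of dim probes by construction, while the cause of the reversals was not tested.

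Under quantile normalization the shifts of the mevalonate pathway (-0.0027), peroxisomal beta-oxidation (-0.31), mitochondrial fatty acid oxidation (-0.075), nuclear hormone receptors (0.051) and histones (-0.0051) lost their calls, that of ribosomal proteins reversed (0.10) and 3 lists passed. With normexp and quantile together the number of genes past the threshold and at least 2-fold was 924. col-130 (0.043), mup-2 (0.16) and glh-1 (0.014) reversed, as did the ribosomal shift (0.054). The mevalonate (-0.031), peroxisomal (-0.32), mitochondrial (-0.10), receptor (0.045) and histone (-0.030) shifts lost their calls and 3 lists passed. In the deposited value table there were 775 such genes, and col-130 (0.032), mup-2 (0.33) and glh-1 (0.23) reversed. These genes were each saturated on 4 wild-type and 4 mutant arrays, all of the second set. Scaling therefore sets their difference in that set, as for most ribosomal genes, and their reversals are not read as expression. In that table the mevalonate (-0.024), peroxisomal (-0.34), mitochondrial (-0.10), receptor (0.063), ribosomal (-0.0032) and histone (-0.046) shifts lost their calls, with 3 lists called. The cause of the changes in the other lists was not tested.

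With no filter the fatty acid (-0.36) and intestine (-0.15) lists gained a call and nuclear hormone receptors (0.066) lost it. With a strict filter C-type lectins (0.16) gained a call and histones (-0.17) lost theirs. At an adjusted p of 0.01, 3500 genes passed. The number of genes past the threshold in both array sets, same direction, was then 1558, and 4847 genes had a difference between array sets, as a stricter threshold gives.

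Without the array set, 1749 genes passed (941 genes higher in the mutant, 808 genes lower in the mutant) and the number of genes past the threshold and at least 2-fold was 766, since differences between the sets then add to the spread. The mevalonate (-0.15), peroxisomal (-0.50), receptor (0.11) and ribosomal (-0.12) lists lost their calls, and the fatty acid (-0.35) and moulting (-0.45) lists gained them. With slide as a block the fatty acid (-0.47) and moulting (-0.59) lists gained a call, and receptors (0.10) and histones (-0.14) lost theirs.

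With replicate number as a block, which treats equal numbers as a pairing, 3696 genes passed (1497 genes higher in the mutant, 2199 genes lower in the mutant) and the number of genes past the threshold and at least 2-fold was 761. The numbers show little sign of pairing: 2 of 7 pairs correlated above 0.1 (range -0.01 to 0.17), and 2 wild-type arrays correlated best with the mutant array of their own number.

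In the first array set alone, 913 genes changed at least 2-fold. sams-1 (0.15), mtrr-1 (0.023), vit-5 (-0.30), dnj-27 (0.083), nekl-2 (0.055), noah-1 (0.20), his-70 (-0.98), gpd-1 (-0.062), dpy-7 (0.27), nspd-3 (-0.89), nspd-1 (-1.27), ncr-2 (-0.45) and strm-1 (0.46) reversed. The shifts of the moulting cycle (0.28), ribosomal proteins (0.021), germline markers (-0.054) and sperm markers (-1.23) reversed. Those of the mevalonate pathway (-0.090), peroxisomal beta-oxidation (-0.40), mitochondrial fatty acid oxidation (-0.12) and F-box genes (0.077) lost their calls and 4 lists passed. In the second set alone, 2728 genes changed at least 2-fold. The mevalonate (-0.13), receptor (0.14) and histone (-0.10) lists lost their calls, and the fatty acid (-0.56), moulting (-0.86), intestine (-0.18) and body wall muscle (-0.19) lists gained them. The cause was not tested.

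With array weights the number of genes past the threshold and at least 2-fold was 616 and the list of germline markers (0.10) lost its call. Mutant replicate 7 had the lowest weight (0.168). With the sperm level as a covariate there were 582 such genes, and the mevalonate (-0.13), mitochondrial (-0.19), receptor (0.11), ribosomal proteins (-0.034), histone (-0.16) and germline markers (0.021) lists lost their calls, leaving 3.

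Without the 500 genes saturated on any array, 6064 genes passed and the number of genes past the threshold and at least 2-fold was 1504. The same 9 lists passed. The shift of ribosomal proteins was then -0.38, but from 7 of 74 genes. The lists of ribosomal proteins and body wall muscle markers no longer passed the test of the difference between sets (adjusted p = 0.286 and 0.205). Of their genes, 66 and 7 lie at the ceiling on all arrays of the second set. The 8 muscle markers left were still shifted by -0.19 in that set, so the smaller number of genes could also account for the lost call.

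With an estimated correlation 0 lists passed. The 9 that lost their calls, with unchanged shifts, were mevalonate (-0.15), peroxisomal (-0.50), mitochondrial (-0.26), receptors (0.11), F-box (0.24), ribosomal (-0.12), histones (-0.18), germline (0.25) and sperm (3.00). The fry test called 21 lists. It tests each list on its own and not against other genes. It added sterol hormone (0.15), fatty acid (-0.35), lipases and lipid storage (0.0037), vitellogenins and yolk uptake (0.069), UDP-glucuronosyltransferase (-0.15), P-glycoproteins and ABC transporters (-0.059), short-chain dehydrogenase (-0.14), heat shock (-0.12), insulin (-0.13), C-type lectins (0.053), antimicrobial (0.16), housekeeping (-0.10), intestine (-0.13) and body wall muscle markers (-0.079), and left out histones (-0.18) and germline (0.25). The values are median shifts. For the sterol hormone, lipase, vitellogenin and antimicrobial lists fry called the direction lower, against the sign of the median shift. The sterol hormone list holds nhr-8, the mutated gene itself (-2.53), and its mean log2 fold change with nhr-8 was -0.01. That fry call was therefore partly fixed in advance and is not read as a fall of the other members.

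Leaving out each array in turn, the number of genes at least 2-fold changed ranged from 941 to 1801. The fatty acid shift ranged from -0.43 to -0.30, nuclear hormone receptors from 0.085 to 0.13, histones from -0.23 to -0.094 and germline from 0.20 to 0.30, each with calls gained or lost. The number of genes past the threshold ranged from 4884 to 6544 and nhr-8 from -2.59 to -2.51. The calls of daf-12, ncr-2, his-70, nspd-1 and nspd-3 over all arrays were each lost in 8 of the 14 fits.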

Other observations

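The split of the 378 genes by gene family and chromosome was looked at only after these genes were known. The test of the sperm level on them was chosen after the result was seen for named genes among them. The tests of linkage and of neighbouring copies were set before their results were seen.

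Among the genes changed at least 2-fold one way in both array sets, a few gene families held more members than their size gives (one-sided hypergeometric tests over 383 families with at least 5 tested members and both directions, Benjamini-Hochberg adjusted). Of 21 tested claudin-like clc genes, 9 were higher (adjusted p = 1.12e-08). C-type lectins were over-represented both ways, with 14 of 136 higher (adjusted p = 9.27e-06) and 11 lower (adjusted p = 9.27e-06), and so were cytochrome P450 genes, with 7 of 66 higher (adjusted p = 0.00958) and 5 lower (adjusted p = 0.0244). Of 135 fbxa F-box genes, 13 were higher (adjusted p = 4.64e-05). Also higher were 4 of 23 arrestin-domain arrd genes (adjusted p = 0.0269), 4 of 22 sri genes (0.0244), 3 of 8 srr genes (0.0186) and 3 of 11 zip genes (0.034). Families over-represented among the lower genes were 4 of 9 lysozyme lys genes (adjusted p = 0.000121), 4 of 21 saposin-like spp genes (0.0044), 4 of 33 carboxylesterase cest genes (0.0186), 3 of 16 scl genes (0.0244, with 3 more higher) and 2 of 5 ilys genes (0.0414).

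These genes were spread unevenly over the genome. Chromosome V held 155 of the 369 that have a place in the gene table, or 4.91% of its tested genes (Fisher's exact test, adjusted p = 2.9e-18 over 6 chromosomes). Chromosomes I (0.708% of its tested genes, adjusted p = 2.87e-11), X (1.29%, adjusted p = 8.49e-05) and III (1.59%, adjusted p = 0.00227) held fewer than the rest, and II (2.47%, adjusted p = 0.888) and IV (3.10%, adjusted p = 0.0661) did not pass. In gene order, 123 of the 369 lay next to another of them among tested genes, against a median of 18 and at most 39 in 1000 random draws. The tests by chromosome and by family treat genes as independent, which neighbouring changed genes are not. Their p-values are therefore too small.

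Background variants that act on genes within 200 genes either side of nhr-8 are argued against as the main cause of these changes. Of the genes, 3.25% lay within 200 genes either side of nhr-8, against 2.45% of tested genes (Fisher's exact test, p = 0.302). A linked variant that acts on genes elsewhere would not be seen by this test and stays open. So does a linked stretch of the chromosome longer than this window. Chromosome IV, which carries nhr-8, held 75 of the 369 genes (3.10% of its tested genes, Fisher's exact test, adjusted p = 0.0661). Signal shared between neighbouring copies of a gene on the array stays open. By name, 13.6% lay next to another with a shared stem, but genes known by sequence name only cannot share one, and 33.3% lay next to another changed gene of any name. A difference in age stays open too. With the sperm level as a covariate 99.7% of the genes kept their direction and stayed past the threshold, but they were picked for one sign in both sets, where the sperm level runs opposite ways, so this could hardly come out otherwise. Strain differences elsewhere in the genome, which could also cluster on chromosome V, and an effect of nhr-8 on gene clusters both stay open, since 1 mutant strain was compared.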
